A study of Mus musculus with 26 samples.

How the data were processed

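Total RNA of mouse neural stem cells had been biotin-labelled and read on an Affymetrix array, per the labels. The deposited values are on a log2 scale, as read from their range of 0.22 to 14.6 and from array medians that lie close together within each set. The sources used here do not state how the values were normalized. The 18 arrays of the pool set and the 8 arrays of the suppression set had medians of their own and look normalized apart, so no comparison crossed the sets. No value was missing, and each of the 26 columns mapped to 1 sample.

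The deposited values covered 269751 probe sets. Of these, 233753 named 1 gene symbol, 5106 named several and 30892 named none. A gene's value was the mean of the log2 values of all probe sets that named that symbol alone, with a median of 8 probe sets per gene, and 23152 genes were tested with no filter on dim signal. Symbols were matched to the RefSeq mouse annotation: 20875 were current, 2189 were updated through a unique synonym and 88 were not matched. The genome build behind the array was not stated, so no positions are given. Probe sets that named several genes or none were not used in the gene tests. The single probe sets of Myb (18) and Qk (15) were also tested, and so was every probe set on its own.

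Samples were grouped by construct and by suppressed gene as the labels give them. The 2 eGFP arrays of a pool were averaged, so that each pool counted once, and the 15 resulting columns of the 5 construct groups were fitted together in limma 3.58.1 under R 4.3.3 and data.table, version 1.17.8. The 8 suppression arrays were fitted apart. Each fit used group means and moderated variances (lmFit, contrasts.fit and eBayes). The comparisons were each construct against eGFP, the 3 pairs of MYB constructs, and Qk suppression against LacZ suppression. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called, and called means this throughout. Log2 fold changes are differences of group means on the log2 scale. The labels do not say that pools or numbered samples came from separate animals or cultures, so p-values measure the spread between these samples. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

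Samples that share a pool number proved to be alike after group means were removed. The 30 pairs of pool samples with the same number had correlations of 0.31 to 0.72, with a median of 0.53, against a median of -0.23 for the 60 other pairs. The 5 pairs of suppression samples with the same second number had 0.22 to 0.57, with a median of 0.32, against -0.21 for the 10 other pairs. By a rule set beforehand, values from a fit with the number as a block therefore stand beside a printed list, count or gene where they change its call or move its count by more than 1.5 times. The SD of the difference between 2 eGFP arrays was 0.25 to 0.27 within a pool and 0.36 to 0.51 between pools. The first principal component of the 15 columns, with 36.0% of the variance, ordered the pools, and the next, with 22.2%, set the MYB constructs apart from eGFP and QKItr.

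There were 21 gene lists: described MYB targets, MYB and STAR family members, markers of neural stem cells, oligodendrocyte precursors, myelinating oligodendrocytes, astrocytes, neurons, microglia and immune cells, vascular cells and fibroblasts, and genes of S phase, G2 and M phase, the interferon response, p53 targets, MAPK output, immediate early response, Notch targets, the integrated stress and unfolded protein response, cholesterol synthesis, endosome and lysosome, and extracellular matrix and adhesion. Some list members are not reported here. Lists were tested with camera of limma at its preset correlation of 0.01 and again with an estimated correlation, and adjusted over the 21 lists of a comparison. Members were counted over all genes and adjusted over the list alone. Of the 21 list calls at the preset correlation, 3 held with an estimated one: precursor markers with MYBtr and MYBQKI6, and MYB and STAR family members with MYBQKI6. With the pool block and an estimated correlation none of these 3 was called (adjusted p = 0.090, 0.092 and 0.092). The MYB and STAR family list holds Myb itself and was not tested without it.

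The groups, lists, tests of the comparisons, naming rule and most alternatives were chosen before the data were examined, and the closing section names the tests and alternatives chosen later. Genes were named if they were called with the same direction in every pool, taking the 10 largest rises and the 10 largest falls for a construct against eGFP and for Qk suppression, and 5 each way for pairs of constructs. Predicted, clone and small RNA names were left out by this rule. Myb and Qk were always named, as were up to 4 members of each list with the smallest p. The Qk difference was also tested with an exact two-sided permutation test.

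The fits were tested on simulated data with the same spread: 200 of 23152 genes were changed in 20 draws. MYBQKI6 against eGFP recovered 62.2% of genes changed by a log2 of 1 and 95.0% of those changed by 2, with 1.2 false calls on average. With the block these were 87.5% and 99.5%, with 10.1 false calls. Qk suppression recovered 42.9% and 93.0%, with 0.9 false calls, and with the block 65.8% and 96.3%, with 6.65 false calls. A list raised by 0.5 was called by camera in 20 of 20 draws, with 0.15 other lists called on average. Noise was drawn for each gene on its own, so beyond pool differences the simulated genes were not correlated. These draws therefore do not show how often camera at its preset correlation calls lists falsely in the real data.

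Alternatives were the pool or second number as a fixed block, the pool as a random block over all 18 arrays, the 6 eGFP arrays as separate samples, only the 2 groups compared, all 26 arrays in 1 fit, quantile normalization, median centring, removal of probe sets under percentile 25 of mean signal, another summary of a gene's probe sets (the median, or the probe set with the highest mean), single probe sets, eBayes with trend and robust, averaging, leaving out or taking alone the Qk samples of a first number, a random block by first number, and leaving out each pool or sample in turn. Correlations were repeated with Spearman's coefficient, without dim probe sets and without the MYB and STAR family. Splits of the same samples into groups of the same sizes were refitted in each comparison, 10 for 3 against 3 and 56 for the suppression set.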

Results

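Gene expression was measured on Affymetrix arrays in neural stem cells isolated from E14.5 embryos of C57BL6 wild-type mice. Lentivirus delivered a transgene to every sample. The series asked what MYBQKI does to these cells and what suppressing the cells' own Qk adds. MYBQKI joins MYB, a transcription factor, to QKI, an RNA-binding protein of the STAR family, and the fusion is known from angiocentric glioma, a brain tumour of children. Qk is the mouse gene for QKI, and the names QKI5 and QKI6 are used for splice forms of it. The 26 arrays formed 7 groups in 2 sets. In the pool set of 18 arrays, cells of pools 1 to 3 carried MYBtr, MYBQKI5, MYBQKI6 or QKItr, with 3 arrays each, or the control protein eGFP, with 6 arrays from 2 repeats per pool. In the suppression set of 8 arrays, cells with MYBQKI6 also had Qk suppressed in 5 samples or LacZ, a bacterial control target, in 3 samples. The labels do not say what tr stands for or what the first numbers 5, 6 and 9 of the Qk samples mean. Array medians lay between 5.61 and 5.74 on the log2 scale in the pool set and between 5.39 and 5.51 in the suppression set, so values were tested only within a set. The number of arrays limits the precision of every value.

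Cells given a MYB construct carried more Myb signal, while the signal of Qk as a whole gene was not called different with any construct. Myb, the proto-oncogene from which the constructs take their name, had a mean log2 signal of 4.62 ± 0.49 (SD, n = 3 pools) with eGFP. It reached 7.23 ± 0.12 with MYBtr, 6.99 ± 0.31 with MYBQKI5 and 7.46 ± 0.40 with MYBQKI6, each over 3 pools. The rises were 2.62 (SE 0.27, 6.14-fold, limma adjusted p = 2.6e-04), 2.37 (5.17-fold, adjusted p = 0.0019) and 2.84 (7.16-fold, adjusted p = 3.5e-04), and each was seen in 3 of 3 pools. QKItr left Myb at 4.86 ± 0.42, a difference of 0.24 with a 95% confidence interval of -0.34 to 0.82. The brightest response came from probe set 17239679 of Myb, which stood at 6.66 ± 0.52 with eGFP and at 7.44 ± 0.36 with QKItr. It reached 12.37 ± 0.27, 12.30 ± 0.43 and 12.37 ± 0.46 with the 3 MYB constructs. Probe set 17239681 stayed at 0.99 to 2.44 on the pool arrays, so the gene mean averages probe sets that rose with others that did not. Myb probe sets may read the delivered construct, and this was not separated from the cells' own Myb. Of the 18 Myb probe sets, 7, 6 and 6 were called with MYBtr, MYBQKI5 and MYBQKI6 over all probe sets (7, 6 and 7 with the pool as a block), and 12, 9 and 11 when adjusted over the list alone. Qk differed from eGFP by -0.28 (SE 0.17, adjusted p = 0.74) with MYBtr, by -0.10 with MYBQKI5, by -0.11 with MYBQKI6 (95% confidence interval -0.48 to 0.26) and by 0.25 with QKItr (-0.12 to 0.61). No Qk probe set was called against eGFP with any construct, also when adjusted over the 15 Qk probe sets. Probe set 17340760 stood at 11.2 with eGFP, 10.94 with MYBtr, 12.14 with MYBQKI5, 10.98 with MYBQKI6 and 12.25 with QKItr. Its differences of 1.20 between MYBQKI5 and MYBtr and of -1.16 between MYBQKI6 and MYBQKI5 had adjusted p values of 0.024 and 0.030 over the 15 Qk probe sets, and 0.77 and 1.00 over all probe sets in limma.

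**Figure D1:**
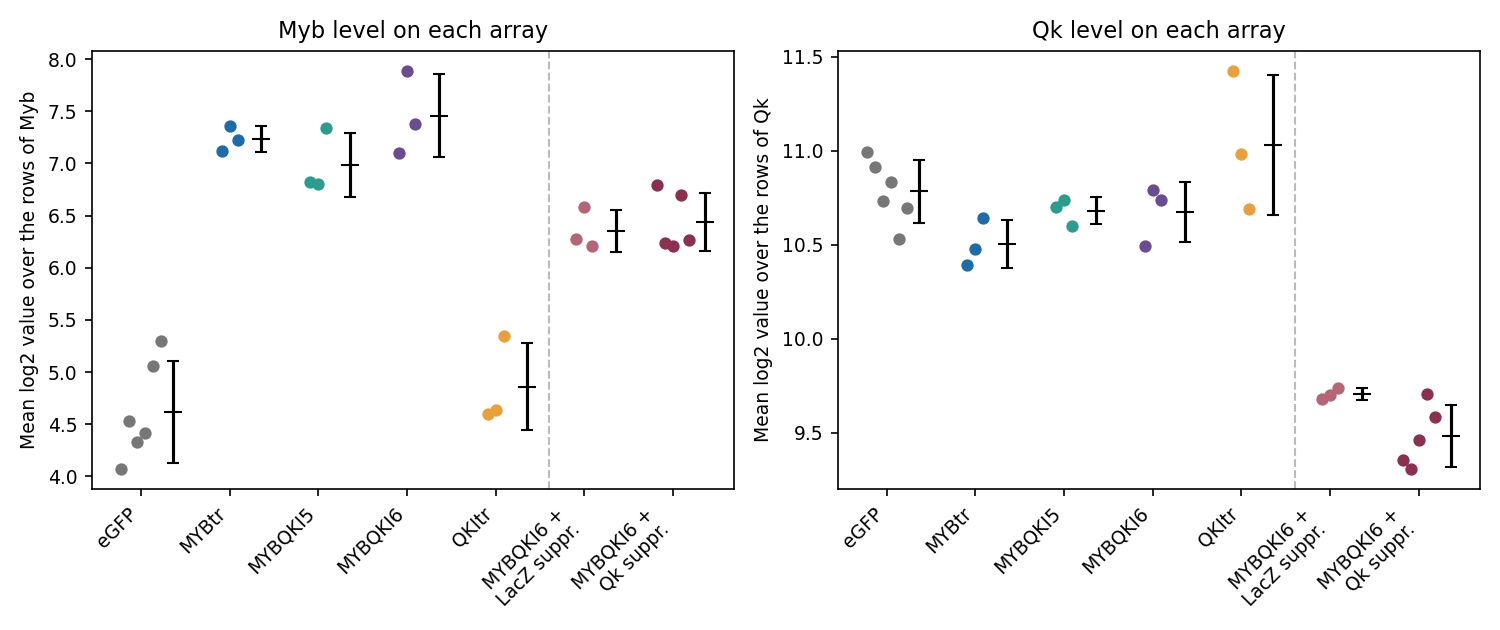
Mean log2 signal of Myb and Qk in each of the 26 arrays, with points for arrays, group mean and SD, and a dashed line between the pool set and the suppression set. Group means of Myb were 7.23, 6.99 and 7.46 with the 3 MYB constructs against 4.62 with eGFP, and Qk had means of 9.48 and 9.70 in the Qk and LacZ suppression samples.

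Kit, the receptor for stem cell factor and a described target of MYB, rose by 2.96 (SE 0.33, 7.78-fold, adjusted p = 6.2e-04) with MYBtr. Its mean log2 signal went from 5.64 with eGFP to 8.60. The other changes in this paragraph are also those of MYBtr against eGFP. Cdk6, a kinase of the G1 phase of the cell cycle, rose by 2.28 (adjusted p = 2.4e-04). Prune2 showed the largest rise among the named genes, 4.06 (SE 0.24, 16.7-fold, adjusted p = 1.9e-06), and Zmynd10, which is needed to build the dynein arms of motile cilia, rose by 3.52 (SE 0.35, adjusted p = 2.4e-04). Prelp, a leucine-rich proteoglycan of the extracellular matrix, rose by 3.08 (adjusted p = 2.4e-04), Fras1, a basement membrane protein, by 2.51 (adjusted p = 2.4e-04), and Fn1, which encodes fibronectin, by 3.05 (SE 0.61, adjusted p = 0.025). Itga5, which encodes a chain of the fibronectin receptor, rose by 1.61 (adjusted p = 0.017). Other large rises were those of Frat2, a regulator of GSK3 (2.58, adjusted p = 0.0079), Abca9, a membrane transporter (2.79, adjusted p = 0.018), and Mup6 (3.94, SE 0.91, adjusted p = 0.049). Mup6 belongs to a family of near-identical genes, and whether its probe sets tell the members apart was not tested. The eGFP means of Mup6 (2.27) and Abca9 (3.43) lay below percentile 25 of the signals on every eGFP array, so the exact size of these 2 rises is uncertain. The largest falls were those of Fbxo32, a subunit of a ubiquitin ligase (-2.40, SE 0.28, adjusted p = 8.9e-04), Xylt1, which starts glycosaminoglycan chains (-2.16, adjusted p = 0.046), Cyp2j9 (-1.97, adjusted p = 0.0029) and Ttyh1 (-1.94, adjusted p = 0.0099). Further falls were those of Sox8, a transcription factor of the oligodendrocyte lineage (-1.91, adjusted p = 0.030), Gjc3, a connexin (-1.86, adjusted p = 0.012), Hepacam, an adhesion protein of glia (-1.65, adjusted p = 0.022), Ptgds, which makes prostaglandin D2 (-1.63, adjusted p = 0.017, but -0.18 and not called when its probe set with the highest mean stood for the gene), and Gfap, the astrocyte filament protein (-1.40, adjusted p = 0.033). Fos, an immediate early transcription factor, fell by 1.86 (adjusted p = 0.016), and Shc4, a signalling adaptor, fell by 1.67 (adjusted p = 0.018).

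In limma, MYBtr against eGFP called 317 of 23152 genes, 208 higher and 109 lower, and 178 of the calls were at least 2-fold. With the pool as a block, 1383 genes were called, 772 higher and 611 lower, and these included all 317. Each gene named above changed in the same direction in 3 of 3 pools. The count without a block depended on single pools: it was 52 without MYBtr of pool 2, 82 without MYBtr of pool 1, 65 without eGFP of pool 2, 74 without eGFP of pool 1 and 125 without eGFP of pool 3. Of the 20 genes named for size of change, Cyp2j9, Fbxo32, Fras1, Kit, Myb, Prelp, Prune2 and Zmynd10 were called in each of these and in the fit without MYBtr of pool 3. Between 6 and 12 of the 20 lost the call in the fits without MYBtr of pool 1 or 2 or without eGFP of any pool.

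With MYBQKI5, a fusion of MYB to QKI, the 10 largest named rises were in genes that MYBtr also raised. Kit rose by 2.55 (SE 0.33, 5.86-fold, adjusted p = 0.0044) and Cdk6 by 1.51 (adjusted p = 0.017). Zmynd10 rose by 2.94 (adjusted p = 0.0021) and Prune2 by 2.86 (SE 0.24, 7.24-fold, adjusted p = 1.0e-04). Dgkg, which encodes a diacylglycerol kinase, rose by 2.42 (adjusted p = 0.0019), Kif26b, a member of the kinesin family, by 2.36 (adjusted p = 0.0019), and the matrix genes Prelp and Fras1 by 2.22 (adjusted p = 0.0080) and 2.16 (adjusted p = 0.0019). Anks1, which encodes an ankyrin repeat protein, rose by 1.93 (SE 0.16, adjusted p = 1.0e-04) and Tmod1, an actin-capping tropomodulin, by 1.89 (adjusted p = 0.010). The falls were smaller. Fbxo32 fell by 1.64 (adjusted p = 0.040), Ptprv, a receptor-type phosphatase, by 1.53 (adjusted p = 0.045), Lifr, the receptor for leukaemia inhibitory factor, by 1.26 (adjusted p = 0.040) and Plxna2, a semaphorin receptor, by 1.05 (SE 0.12, adjusted p = 0.0019). Nxph1, a neurexin ligand (-1.04, adjusted p = 0.039), Dok7 (-1.01, adjusted p = 0.049), Ank (-0.94, adjusted p = 0.045), Arnt2, a transcription factor (-0.93, adjusted p = 0.017), Ptar1 (-0.86, adjusted p = 0.049) and Mageh1 (-0.84, adjusted p = 0.047) made up the rest of the named falls. With the probe set of highest mean standing for the gene, Dok7 turned to 0.10 and Ptar1 stood at -0.23, and neither was called. Fn1 differed by 2.32 with an adjusted p of 0.18, which was 0.0057 with the pool as a block.

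MYBQKI5 against eGFP called 46 genes in limma, 32 higher and 14 lower, 29 of them at least 2-fold. The pool block gave 609 genes, 295 higher and 314 lower, with all 46 among them. Each named call above pointed the same way in 3 of 3 pools. Counts fell to 11 without MYBQKI5 of pool 3, 15 without MYBQKI5 of pool 2, 14 without eGFP of pool 2, 15 without eGFP of pool 1 and 21 without eGFP of pool 3. Anks1, Dgkg, Fras1, Kif26b, Kit, Myb, Plxna2, Prune2 and Zmynd10 were called in every fit that left out 1 pool of either group, and the other 11 of the 20 genes named for size lost the call in at least 1 of them.

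MYBQKI6, the fusion used for the suppression samples, raised many of the genes that MYBtr raised. Prune2 rose by 3.60 (SE 0.24, 12.1-fold, adjusted p = 9.4e-06), Zmynd10 by 3.08 (adjusted p = 0.0011) and Kit by 2.80 (SE 0.33, 6.95-fold, adjusted p = 0.0012). Cdk6 rose by 1.88 (adjusted p = 0.0017), and Ada, which encodes adenosine deaminase and is a described MYB target, by 1.16 (adjusted p = 0.0036). Further large rises were those of Dgkg (2.77, adjusted p = 5.5e-04), Mcub, a subunit of the mitochondrial calcium uniporter (2.77, adjusted p = 0.0011), Prelp (2.43, adjusted p = 0.0023), Kif26b (2.38, adjusted p = 0.0011), Frat2 (2.34, adjusted p = 0.019) and Tnfaip6, a hyaluronan-binding protein (2.27, adjusted p = 0.0047). Fbxo32 fell by 1.92 (SE 0.28, adjusted p = 0.0073). Ptgds fell by 1.65 (adjusted p = 0.022), Ednrb, the endothelin receptor B, by 1.54 (adjusted p = 0.042) and Cspg4, which encodes the precursor marker NG2, by 1.36 (SE 0.27, adjusted p = 0.037). The remaining named falls were those of Kcnma1, a potassium channel (-1.64, adjusted p = 0.045), Cyp2j9 (-1.64, adjusted p = 0.014), Ttyh1 (-1.62, adjusted p = 0.032), Rev3l, the catalytic subunit of DNA polymerase zeta (-1.48, adjusted p = 0.036), Gdpd2 (-1.45, adjusted p = 0.046) and Tnfrsf21, a death receptor (-1.40, adjusted p = 0.030). Sox8 differed by -1.79 with an adjusted p of 0.058, or 0.0021 with the pool as a block, and Gfap by -1.32 with 0.060, or 0.0092 with the block.

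The limma comparison of MYBQKI6 with eGFP called 177 genes, 124 higher and 53 lower, of which 106 were at least 2-fold. The pool block called 1017, 555 higher and 462 lower, and kept all 177. Each named call had the same direction in 3 of 3 pools. Leaving out single pools gave 23 genes without MYBQKI6 of pool 2, 38 without MYBQKI6 of pool 1, 35 without eGFP of pool 2, 39 without eGFP of pool 1 and 69 without eGFP of pool 3. Dgkg, Kif26b, Kit, Mcub, Myb, Prelp, Prune2, Tnfaip6 and Zmynd10 kept the call in every such fit, and the other 11 of the 20 genes named for size did not. When the probe set with the highest mean stood for the gene, Ptgds stood at -0.27 (adjusted p = 1.00), Gdpd2 at -0.75 (0.36) and Mcub at 1.56 (0.16).

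**Figure D2:**
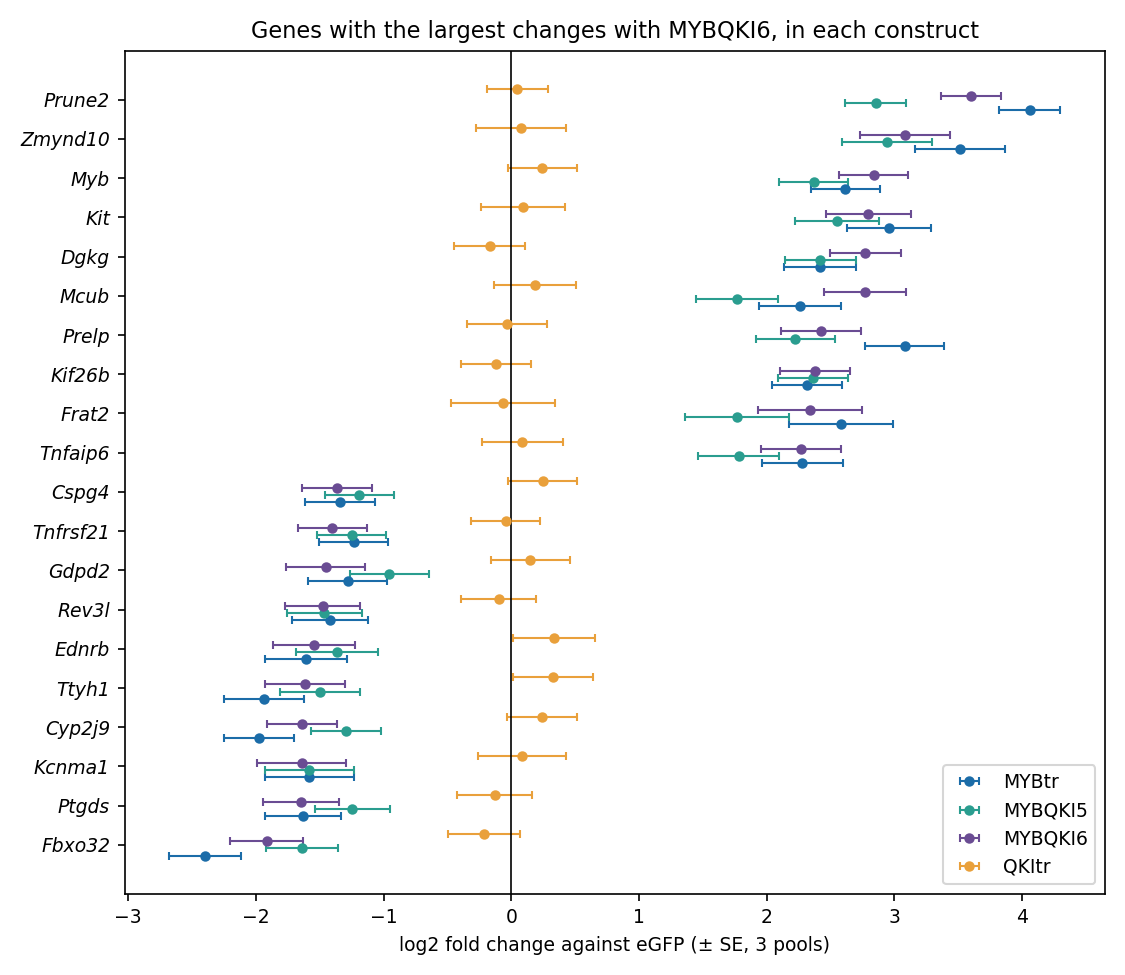
Log2 fold change against eGFP, with bars of 1 SE over 3 pools, of the 10 largest rises and 10 largest falls named for MYBQKI6, drawn for the 4 constructs. Prune2 stood at 4.06, 2.86 and 3.60 with MYBtr, MYBQKI5 and MYBQKI6, and Fbxo32 at -2.40, -1.64 and -1.92.

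The 3 MYB constructs shared most of the genes called with the smaller lists. Kit, Prune2, Zmynd10, Prelp, Fras1, Kif26b, Dgkg, Anks1, Tmod1 and Cdk6 rose with each of them, and Fbxo32 fell with each of them. In all, 43 genes were called with the 3 constructs, 32 higher and 11 lower, and 496 with the pool as a block, 252 higher and 244 lower. MYBtr and MYBQKI6 shared 99 genes called higher and 44 called lower, where independent lists of the same lengths would share 1.11 and 0.250. MYBtr and MYBQKI5 shared 32 and 12 (0.287 and 0.0659 for independent lists), and MYBQKI5 and MYBQKI6 shared 32 and 13 (0.171 and 0.0320). The comparisons use the same eGFP arrays, which by itself can make their fold changes alike. Across genes, which are not independent replicates, the Pearson correlation of fold changes was 0.776 for MYBtr with MYBQKI5, 0.828 for MYBtr with MYBQKI6 and 0.822 for MYBQKI5 with MYBQKI6. Groups simulated without any change against the same controls gave a mean correlation of 0.512, with a range of -0.252 to 0.844 that takes in the 3 real values. This simulation drew residuals of the fit with the pool block at random, without keeping pools together, and gave 1 set of values for all pairs. The covariances were 0.0633, 0.0750 and 0.0628, above the highest simulated covariance of 0.0368. With eGFP repeats R1 used for 1 construct and R2 for the other, the correlations were 0.683, 0.736 and 0.709, although the repeats came from the same pools. QKItr gave correlations of 0.046, 0.164 and 0.074 with MYBtr, MYBQKI5 and MYBQKI6, with covariances of 0.0023, 0.0069 and 0.0034 that lay below the simulated mean of 0.0150. Split controls gave -0.041, 0.045 and -0.020 for these 3 pairs.

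Markers of oligodendrocyte precursors, the cells that give rise to myelin-forming glia, were lower as a list with each MYB construct. The list mean was below that of eGFP in 3 of 3 pools with MYBtr, MYBQKI5 and MYBQKI6. With MYBtr, 2 of 14 markers were positive, with a median change of -0.53 (camera adjusted p = 2.0e-06, and 0.036 with an estimated correlation). With MYBQKI6, 3 of 14 were positive, with a median of -0.40 (adjusted p = 3.0e-06, and 0.023 with an estimated correlation). With MYBQKI5, 4 of 14 were positive, with a median of -0.39 (adjusted p = 0.0010). For MYBQKI5 the list had an adjusted p = 0.12 with an estimated correlation. With the pool block and an estimated correlation none of the 3 was called (adjusted p = 0.090, 0.18 and 0.092 for MYBtr, MYBQKI5 and MYBQKI6). Over all genes 2 members fell with MYBtr, Sox8 and Cspg4 (-1.34, adjusted p = 0.027), none with MYBQKI5 and Cspg4 with MYBQKI6. In each comparison 6 members were called lower when adjusted over the list alone, and 7 were called over all genes with the pool as a block: Olig1, Olig2, Cspg4, Lhfpl3, Sox6, Sox8 and Pcdh15. Some other members did not follow. Pdgfra was higher by 0.67 over the 3 MYB constructs together (limma with the pool block, adjusted p = 0.031). Sox10, Nkx2-2, Gpr17, Neu4 and Matn4 lay below the median gene with eGFP, at 4.69, 4.26, 4.36, 4.74 and 4.32. Their changes in the same fit were -0.13 to 0.034. Olig2, a transcription factor that specifies the lineage, differed by -0.64, -0.63 and -0.59, with adjusted p values of 0.066, 0.15 and 0.13, or 0.022, 0.042 and 0.042 with the pool block. The list of myelinating oligodendrocyte markers was not called (adjusted p = 0.85, 0.61 and 0.38), though its member Cnp rose by 0.79 with MYBtr (adjusted p = 0.035) and by 1.02 with MYBQKI6 (adjusted p = 0.014). With MYBQKI5 Cnp differed by 0.79 (adjusted p = 0.085, and 0.0089 with the pool block).

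Astrocyte markers were lower with MYBtr (6 of 17 positive, median -0.46, camera adjusted p = 0.0013), with an adjusted p = 0.32 with an estimated correlation. With MYBQKI5, 4 of 17 were positive with a median of -0.094 (adjusted p = 0.018, and adjusted p = 0.41 with an estimated correlation). This call was lost without MYBQKI5 of pool 1 (mean change -0.13 against -0.31, adjusted p = 0.57), without eGFP of pool 2 (0.087) and without eGFP of pool 3 (0.11), and when the probe set of highest mean stood for each gene (0.23). With MYBQKI6 the adjusted p was 0.060, and 0.029 with the pool block (adjusted p = 0.39 with an estimated correlation and the block). Adjusted over the list alone, 5, 2 and 1 astrocyte markers were lower, against 1, 0 and 0 over all genes and 7, 3 and 4 with the pool block, which also called Slc4a4 higher each time. Nes, which encodes nestin, a filament protein of neural stem cells, differed by -1.04, -0.96 and -1.11 (adjusted p = 0.061, 0.18 and 0.063, and 0.0032, 0.011 and 0.0031 with the block). Vim, which encodes vimentin, another filament protein of these cells, differed by 0.51, 0.39 and 0.47 (adjusted p = 0.095, 0.43 and 0.17, and 0.0064, 0.047 and 0.012 with the block). With MYBtr the block also called Hes1 (-0.60, adjusted p = 0.22, and 0.010 with the block) and Egfr (-0.67, adjusted p = 0.16, and 0.0499 with the block). The neural stem and radial glia list was not called in any of the 3 (adjusted p = 0.48, 0.82 and 0.78). Lists of neuronal (adjusted p = 0.48, 0.66 and 0.97), vascular (0.54, 0.61 and 0.87) and fibroblast and mesenchymal markers (0.84, 0.091 and 0.63) were not called either. Of their members, the block called 0, 1 and 1 neuronal markers higher and 1, 0 and 1 lower (0 without it), and 1, 1 and 2 fibroblast markers higher (1, 0 and 0 without it). Microglia and immune cell markers were slightly lower with MYBtr (2 of 16 positive, median -0.11, adjusted p = 0.022, and adjusted p = 0.46 with an estimated correlation). That call was lost without eGFP of pool 1 (0.066), without MYBtr of pool 3 (0.12) and with the median over probe sets (0.36). The list had a mean log2 signal of 4.43 with eGFP, below the median of every pool array (5.61 or higher). This dim level limits what the list shows about immune cells. The block called 1 microglia marker, Cd68, lower with each construct (-1.15, -0.92 and -1.10, adjusted p = 0.26, 0.69 and 0.36, and 0.0021, 0.015 and 0.0034 with the block).

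Interferon response genes, which cells switch on in antiviral defence, were higher with each MYB construct and not with QKItr. Within pools, the list mean exceeded that of eGFP by 0.92 to 1.10 with MYBtr, 0.60 to 2.08 with MYBQKI5 and 0.98 to 1.501 with MYBQKI6, and differed by -0.55 to 0.33 with QKItr. With MYBtr, 22 of 23 genes were positive, with a median change of 1.01 (camera adjusted p = 1.8e-07, and adjusted p = 0.46 with an estimated correlation). With MYBQKI5 these values were 22 of 23 and 1.16 (adjusted p = 1.3e-11, and adjusted p = 0.32 with an estimated correlation). With MYBQKI6, 23 of 23 were positive, with a median of 1.26 (adjusted p = 2.8e-12, and adjusted p = 0.35 with an estimated correlation). The size of the list mean depended on single arrays: without eGFP of pool 3 it was 0.53, 0.64 and 0.75 against 1.01, 1.12 and 1.23 with all pools, and without MYBtr of pool 2 it was 0.66 for MYBtr. The list stayed called in these fits at the preset correlation. No single member was called over all genes in limma, and 1, 0 and 1 were called when adjusted over the list alone. The pool block called 9, 8 and 11 members higher. Stat2, a transcription factor of the interferon pathway, differed by 1.36, 1.24 and 1.38, with adjusted p values of 0.068, 0.19 and 0.086, or 0.0032, 0.011 and 0.0038 with the block.

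**Figure D3:**
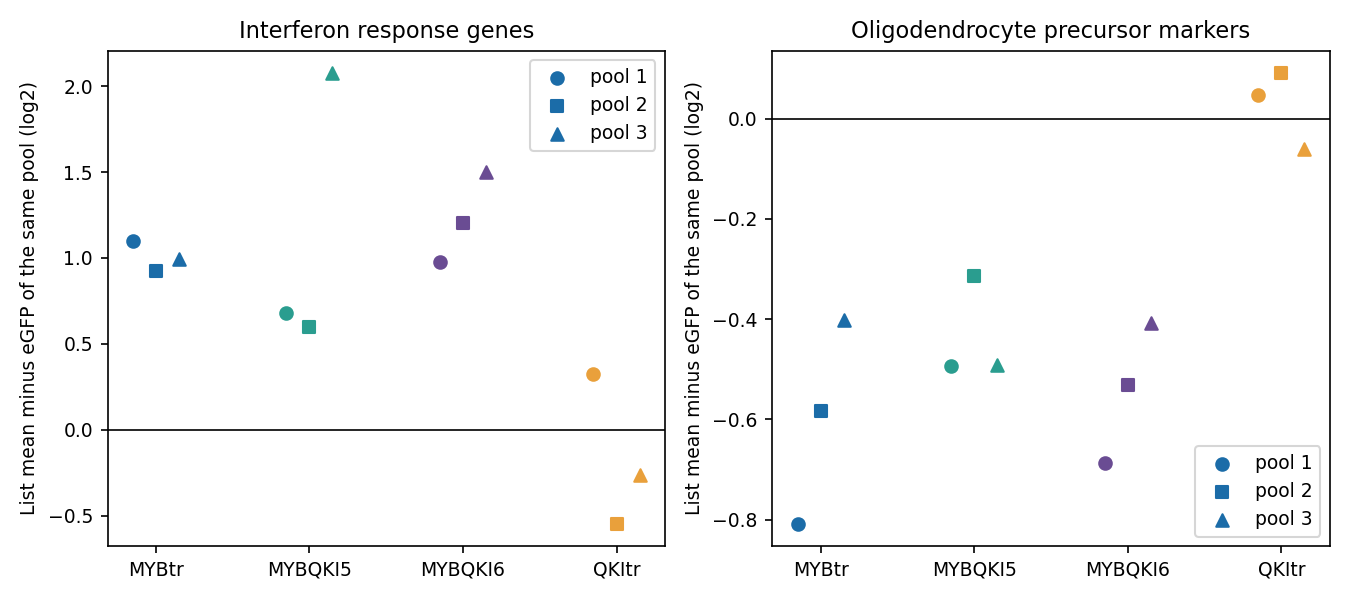
Mean log2 signal of the interferon response genes and of the oligodendrocyte precursor markers minus that of eGFP of the same pool, with 1 point per pool for each of the 4 constructs. Interferon differences with the MYB constructs ran from 0.60 to 2.08, and precursor differences with MYBtr, MYBQKI5 and MYBQKI6 averaged -0.60, -0.43 and -0.54.

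Immediate early genes, which respond within minutes to growth factor signals, were lower with the MYB constructs. With MYBtr, 1 of 16 was positive, with a median of -0.38 (camera adjusted p = 1.8e-06, and adjusted p = 0.18 with an estimated correlation). With MYBQKI5, 4 of 16 were positive, with a median of -0.32 (adjusted p = 2.9e-05, and adjusted p = 0.29 with an estimated correlation), and with MYBQKI6, 3 of 16, with a median of -0.19 (adjusted p = 4.2e-04, and adjusted p = 0.35 with an estimated correlation). Fos and Nr4a1 (-1.33, adjusted p = 0.034) fell with MYBtr over all genes. Adjusted over the list alone, 5, 5 and 3 members were lower, and the pool block called 7, 6 and 5 lower, with Atf3 higher with MYBtr and MYBQKI6. Target genes of p53 were lower with MYBtr (3 of 17 positive, median -0.26, adjusted p = 6.4e-04, and adjusted p = 0.32 with an estimated correlation), MYBQKI5 (3 of 17, median -0.26, adjusted p = 4.9e-04, and adjusted p = 0.32 with an estimated correlation) and MYBQKI6 (4 of 17, median -0.25, adjusted p = 0.0055, and adjusted p = 0.45 with an estimated correlation). For MYBQKI6 the p53 call was lost without eGFP of pool 1 (mean change -0.11 against -0.20, adjusted p = 0.086), and the mean was -0.30 without eGFP of pool 3. For MYBQKI5 the p53 mean was -0.16 without eGFP of pool 1, against -0.25 with all pools, and the list stayed called. Of the p53 targets 3, 1 and 0 were lower when adjusted over the list alone, and 0 over all genes in limma (4, 1 and 1 with the pool block). Output genes of the MAPK pathway were lower with MYBQKI5 (3 of 16 positive, median -0.13, adjusted p = 0.042, and adjusted p = 0.32 with an estimated correlation) and MYBQKI6 (5 of 16, median -0.20, adjusted p = 0.031, and adjusted p = 0.35 with an estimated correlation), and had an adjusted p of 0.079 with MYBtr. Adjusted over the list alone, 1, 1 and 0 MAPK outputs were lower, against 0 over all genes and 2, 2 and 3 with the pool block. These 2 MAPK calls were lost without eGFP of pool 2 (0.29 and 0.25), without eGFP of pool 3 (0.11 and 0.064) and without the construct's own pool 1 (0.47 and 0.22). With the probe set of highest mean standing for each gene, the calls of MYBQKI5 and MYBQKI6 were lost for immediate early genes (mean change -0.14 and -0.10, adjusted p = 0.21 and 0.27), p53 targets (-0.042 and -0.051, adjusted p = 0.23 and 0.40) and MAPK outputs (adjusted p = 0.21 and 0.075). The MAPK call of MYBQKI6 was also lost with the median over probe sets (0.068).

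Described MYB targets as a list were not called with MYBtr, MYBQKI5 or MYBQKI6 (camera adjusted p = 0.58, 0.12 and 0.27). Of the 23 targets 9, 13 and 10 were positive, and with MYBtr and MYBQKI6 the median (-0.080 and -0.031) and the mean (0.16 and 0.20) had opposite signs. Kit and Cdk6 rose with each construct, and Ada rose with MYBtr (0.77, adjusted p = 0.027) and MYBQKI6 and differed by 0.78 with MYBQKI5 (adjusted p = 0.065, and 0.016 with the pool block). Adjusted over the list alone, 4, 3 and 4 targets were higher and 2, 0 and 2 were lower. Myc, a target in blood cells, differed by -0.93, -0.62 and -0.94 (adjusted p = 0.069, 0.52 and 0.092). With the pool as a block the adjusted p of Myc was 0.0090 with MYBtr and 0.011 with MYBQKI6. The block called 4, 3 and 4 targets higher and 2, 0 and 2 lower, against 3, 2 and 3 higher and 0 lower without it. Besides Myc and Ada it added, with MYBtr and MYBQKI6, Bcl2 (0.86 and 0.88, adjusted p = 0.11 and 0.14, and 0.016 and 0.019 with the block) and Gstm1 (-0.86 and -0.71, adjusted p = 0.058 and 0.18, and 0.0032 and 0.012 with the block). The list of MYB and STAR family members, which holds Myb itself, was higher with MYBtr (median 0.22, adjusted p = 0.0044, and adjusted p = 0.079 with an estimated correlation), MYBQKI5 (median 0.20, adjusted p = 0.0019, and adjusted p = 0.097 with an estimated correlation) and MYBQKI6 (median 0.21, adjusted p = 4.3e-04, and 0.023 with an estimated correlation). With the pool block and an estimated correlation the 3 had adjusted p values of 0.18, 0.17 and 0.092, so none was called. The calls of MYBtr and MYBQKI5 were lost with the probe set of highest mean (0.060 and 0.23) and with the median over probe sets (0.052 and 0.29). Adjusted over the list alone, 3, 1 and 2 of its 8 members were higher, and over all genes Myb alone (2, 1 and 2 members with the pool block). The list was not tested without Myb, so its calls are not separate from the rise of Myb. Lists for S phase (adjusted p = 0.39, 0.34 and 0.71), G2 and M phase (0.48, 0.43 and 0.87), Notch targets (0.39, 0.94 and 0.68), the integrated stress response (0.40, 0.94 and 0.78), cholesterol synthesis (0.17, 0.34 and 0.058), endosome and lysosome (0.48, 0.48 and 0.55) and extracellular matrix and adhesion (0.55, 0.96 and 0.97) were not called. Among their members the block called 2, 2 and 2 matrix genes higher and 2, 2 and 3 lower (2, 0 and 0 higher and 0 lower without it), 1, 1 and 0 Notch targets higher and 3, 1 and 1 lower, 2, 0 and 2 stress genes higher and 0, 0 and 1 lysosome genes higher (0 without it). The pool block added G2 and M phase with MYBtr and MYBQKI5 (adjusted p = 0.016 and 0.0076), S phase with MYBQKI5 (0.040) and cholesterol synthesis, lower, with each construct (0.011, 0.047 and 9.2e-04). With the block and an estimated correlation no list was called in any of the 3, and the lowest adjusted p values were 0.062, 0.13 and 0.092.

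QKItr, whose name holds no MYB, changed no gene past the threshold. Myb and Qk were not called, and neither were the genes raised most by the MYB constructs. The limma comparison with eGFP called 0 of 23152 genes, with 362 genes (1.56%) at an unadjusted p under 0.05. Unchanged genes with well-set p-values would give a share near 0.05. Without a block, differences between pools stay in the spread, so these p-values may be too large. The pool block also called 0 genes, with 1064 at an unadjusted p under 0.05. Of the 208 genes called higher and 109 called lower with MYBtr, 105 were positive and 57 negative with QKItr. No list was called, and the lowest adjusted p was 0.23. The block called 2 lists, G2 and M phase genes, higher (adjusted p = 0.014), and MAPK outputs, lower (0.049), and each had an adjusted p = 0.85 with an estimated correlation. Interferon response genes were positive in 5 of 23, with a median of -0.15, and precursor markers had a median of -0.021. Among list members, Mobp, a myelin gene, differed by 0.34 and Myc by -0.56, and neither was called.

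Direct comparisons between the MYB constructs asked whether the QKI part or its splice form changed the response. Kit, Prune2 and Fbxo32 were called with every MYB construct against eGFP, and none of these 3 genes was called between constructs. Cdk6 differed by -0.77 (95% confidence interval -1.27 to -0.28) and Sox9, an astrocyte and stem cell transcription factor, by 0.47 (0.16 to 0.77) between MYBQKI5 and MYBtr, and neither was called. Myb itself differed by -0.25 (-0.83 to 0.33) between MYBQKI5 and MYBtr, by 0.22 (-0.36 to 0.80) between MYBQKI6 and MYBtr and by 0.47 (-0.11 to 1.05) between MYBQKI6 and MYBQKI5. In limma, each of the 3 comparisons called 0 genes, with 849 (MYBQKI5 against MYBtr), 604 (MYBQKI6 against MYBtr) and 404 genes (MYBQKI6 against MYBQKI5) at an unadjusted p under 0.05. These were 3.67%, 2.61% and 1.75% of the genes. They come from the fit without a block, where differences between pools stay in the spread, so its p-values may be too large. The pool block also called 0 in each, with 1926, 1437 and 1017 of 23152 genes at an unadjusted p under 0.05. Calls of 0 genes do not show that the constructs act alike. No list was called, with lowest adjusted p values of 0.062, 0.075 and 0.33. With the block, precursor markers (adjusted p = 0.029) and microglia markers (0.029) were called higher and the integrated stress response (0.031) lower with MYBQKI5 than with MYBtr. Astrocyte markers (0.039), microglia markers (0.039), interferon response genes (0.039) and immediate early genes (0.047) were called higher with MYBQKI6 than with MYBtr. G2 and M phase genes were called lower with MYBQKI6 than with MYBtr (0.015) and with MYBQKI5 (0.0076). None of these 9 calls held, with a lowest adjusted p = 0.65 with an estimated correlation.

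Suppression of Qk in cells with MYBQKI6 was compared with suppression of LacZ, to see what loss of the cells' own Qk adds. Qk had a mean log2 signal of 9.48 ± 0.16 (SD, n = 5) in the samples labelled Qk suppression and 9.70 ± 0.031 (n = 3) with LacZ. The difference was -0.22 (SE 0.15, 95% confidence interval -0.55 to 0.098) and was not called in limma (adjusted p = 1.00). An exact two-sided permutation test over the 56 splits gave p = 0.089, where the smallest possible p was 0.018. The 5 Qk samples stood at 9.35 (5_2), 9.30 (6_1), 9.46 (6_3), 9.70 (9_1) and 9.58 (9_3), each at or below the LacZ mean, and sample 9_1 lay inside the LacZ range of 9.68 to 9.74. Of the 15 Qk probe sets 11 were lower, with changes from -0.82 to 0.80, and none was called. Myb differed by 0.088 (exact permutation p = 0.57).

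In limma 1 of 23152 genes was called in this comparison, with 946 (4.09%) at an unadjusted p under 0.05 (1734 with the second number as a block). The gene was Gm5067, a predicted gene named after its values were seen, which was higher by 1.83 (SE 0.19, adjusted p = 0.017, and 0.0021 with the block). Its mean log2 signal was 4.85 ± 0.32 (SD, n = 5) against 3.02 ± 0.071 (n = 3), and it was above the LacZ mean in 5 of 5 samples. The LacZ level lay below percentile 25 of the signals on every LacZ array, so the exact size of the difference is uncertain. No gene was called without Qk sample 6_1, 6_3 or 9_3, or without LacZ sample 1, 2 or 3 (0 each time). S100b and Aqp4, both astrocyte markers, differed by -0.63 and -0.52 and were not called. Genes of the integrated stress and unfolded protein response were the only list called: 18 of 18 were positive, with a median of 0.27 (camera adjusted p = 0.0023, and adjusted p = 0.96 with an estimated correlation). Sesn2, Herpud1 and Xbp1 had the smallest p among the members (0.54, 0.46 and 0.33), none was called, and 0 were called when adjusted over the list alone. The list call was lost without Qk sample 6_3 (mean change 0.18 against 0.30, adjusted p = 0.16) and without LacZ sample 2 (0.20, adjusted p = 0.078). With the block, neuronal markers (0.027) and G2 and M phase genes (0.0054, with a median of -0.021 without the block) were also called higher and interferon response genes lower (1.4e-07), and none was called with the block and an estimated correlation, where the lowest adjusted p was 0.77.

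Genes that responded to MYBQKI6 showed little common movement with Qk suppression. Across genes, which are not independent replicates, fold changes of MYBQKI6 against eGFP and of Qk against LacZ suppression, which share no array, had a Pearson correlation of 0.052 and a Spearman correlation of 0.061. The 124 genes called higher with MYBQKI6 had a median change of 0.093 with Qk suppression (camera adjusted p = 0.20), and the 53 called lower had a median of 0.013 (adjusted p = 0.87).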

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

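Tests chosen only after the result was seen were those of 1 pool alone and of array scaling for the interferon and precursor lists, of any transgene for the interferon list, and of a wrongly labelled sample and of the QKI part of the construct for Qk. The tests by other splits, of a lower share of precursor cells and of signal near the top of the scale were fixed before.

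Interferon response genes were higher with MYBtr, MYBQKI5 and MYBQKI6. A difference confined to 1 pool was argued against. The smallest of the 9 within-pool differences of the list mean was 0.60, above the SD of 0.44 between pools of the QKItr differences. The constructs of a pool share its eGFP value, so the 9 differences are not independent, and the SD rests on 3 pools. The MYB constructs exceeded QKItr by a mean of 1.28 (SD 0.61, and 0.59 to 1.78 in the 3 pools). QKItr was the only other construct besides eGFP, and no Qk probe set was called with it. Its expression was thus not shown, so these values do not decide about a response to any transgene other than eGFP. The smallest list change was 0.99 after quantile normalization. The deposited pool arrays already had like distributions, with medians of 5.61 to 5.74. This test could therefore hardly come out otherwise and does not decide about array scaling. The list also varied between pools, with eGFP means of 6.47, 7.07 and 5.34: splits that keep each pool on both sides reached list differences of 0.39, 0.72 and 0.58, below the real 1.01, 1.12 and 1.23, while splits that do not reached 1.498, 1.07 and 1.38. An effect of MYB on these genes may remain as a hypothesis, but a difference in viral dose between constructs was not tested and stays open.

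Oligodendrocyte precursor markers were lower as a list with MYBtr, MYBQKI5 and MYBQKI6. A fall in 1 pool alone was argued against by the smallest within-pool fall of 0.31, against an SD of 0.078 for QKItr. Here too the constructs of a pool share its eGFP value, and the SD rests on 3 pools. The smallest fall was 0.42 after quantile normalization, which does not decide about array scaling, since the deposited arrays already had like distributions. A lower share of precursor cells in the cultures stays open. Of 9 abundant markers, 1 had an interval wholly above the list median of -0.44, where the bound set beforehand asked for at least 2. That marker was Pdgfra, a receptor carried by these precursors, which was higher by 0.67 with the 3 MYB constructs together (95% confidence interval 0.29 to 1.04, adjusted p = 0.031). The list median also takes in the dim markers Sox10, Nkx2-2, Gpr17, Neu4 and Matn4, with changes of -0.13 to 0.034. This bound therefore cannot decide about a lower share. Abundant markers did not fall alike: Sox8 had an interval of -2.20 to -1.26 and Sox6 one of -0.72 to -0.35. Olig2 differed by -0.62 (adjusted p = 0.0063). These intervals and p-values are from the limma fit with the pool as a block. Without the block, Olig2 was not called with any single construct. Lower expression of the markers within cells may also be at work, and these arrays of mixed RNA cannot separate it from a lower share.

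Qk was only slightly lower in the samples labelled Qk suppression. A single wrongly labelled sample as the whole cause was argued against. The difference was -0.28 without sample 9_1, which had the highest Qk, against -0.22 with it. Sample 9_1 and the other sample of its first number stood at 9.70 and 9.58. Qk samples with another first number stood at 9.30 to 9.46, and LacZ samples at 9.68 to 9.74. Leaving out 9_1 alone cannot show whether Qk fell less with that first number, which stays open. For the mean over the 15 Qk probe sets, MYBQKI6 minus eGFP had a confidence interval with an upper end of 0.26. This argued against a large rise of that mean through the QKI part of the construct, but cannot decide for single probe sets. Probe set 17340765 stood at 12.24, 12.20 and 12.07 with MYBQKI6 and at 11.41, 11.68 and 11.82 with MYBtr in pools 1 to 3. It stood at 11.78 to 12.05 on the eGFP arrays. No Qk probe set was called between MYBQKI6 and MYBtr, and reading by single probe sets stays open. Signal near the top of the scale could not be decided: across the 15 Qk probe sets, the Spearman correlation of change with LacZ level was 0.19 (permutation p = 0.49), and the Pearson correlation was -0.0086 (permutation p = 0.98). Weak suppression, in all samples or mostly in those with the first number of 9_1, may be the reason. No protein measurement was used here to test it.

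Among splits of the 3 against 3 pool samples, 10 in each comparison, the splits are too few for a share under 0.05. The real split called 317, 46 and 177 genes with MYBtr, MYBQKI5 and MYBQKI6 against eGFP, where the highest other split called 0 each time, so 1 of 10 splits called as many. For QKItr against eGFP, MYBQKI5 against MYBtr and MYBQKI6 against MYBQKI5 the real and the highest other count were 0, and for MYBQKI6 against MYBtr they were 0 and 2, so 10 of 10 splits called as many in these 4. For lists the real split called 7, 7 and 6 with the 3 MYB constructs, and the highest other splits called 12, 8 and 10, with 5, 3 and 5 of 10 splits calling as many. The split that called 12 lists put both pool 1 samples and MYBtr of pool 2 on a side, so it followed the pools in part. Among the 4 splits that keep samples of each pool on both sides, the highest other counts were 0 genes, with and without the block, and 5, 3 and 2 lists. Their highest other list differences were 0.33, 0.22 and 0.27 for precursor markers, for which the real sizes were 0.60, 0.43 and 0.54.

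In the suppression set, chance could not be excluded for the count of genes, since 4 of 56 splits called at least the real 1, nor for the count of lists, since 52 of 56 called at least 1, with a highest other of 8. All 56 splits were counted, also those that follow the second number, so chance was not judged within that number. A split of 5_2, 6_3, 9_3 and LacZ samples 2 and 3 against the rest called 281 genes, which points to a structure of these samples that the groups do not hold. It set the 3 samples of second number 1 apart from all others. A split of 6_1, 9_1, 9_3 and LacZ samples 1 and 3 against the rest called 190, and there samples of second number 3 stood on both sides, so the second number alone does not account for both splits. The cause was not found, and the real split with the second number as a block called 1 gene. A correlation as far from 0 as the 0.052 between MYBQKI6 and Qk suppression was reached by 30 of 56 splits. The other splits ran from -0.14 to 0.13, so chance could not be excluded for it.

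A sample far from the others was sought in 86 tests of 1 gene each, most in the 6 eGFP arrays and the rest in the 5 Qk suppression arrays. In 2 tests there was one. Chance gives about 1 in 20, or 4.3, for independent arrays, but the eGFP arrays are 2 repeats of each of 3 pools. Mup6 had a gap of 0.736 of the group's range in the 6 eGFP arrays, with array 1R2 at 3.14 and the others at 1.86 to 2.20. Sox6 had a gap of 0.659, with eGFP array 1R1 at 7.98 and the others at 8.26 to 8.40. Qk probe set 17340760 differed by -1.16 between MYBQKI6 and MYBQKI5 (limma adjusted p over the Qk probe sets 0.030, and 0.027 with the pool block) and by 1.20 between MYBQKI5 and MYBtr (0.024, and 0.022 with the block). Probe sets that name no gene, which the gene comparisons did not use, were called against eGFP in 39 cases with MYBtr (32 higher, 7 lower), 28 with MYBQKI5 (22 and 6), 33 with MYBQKI6 (26 and 7) and 5 with QKItr (0 and 5). The 5 with QKItr were high only in the eGFP arrays and were called lower with the 3 MYB constructs too, and what they read was not tested.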

How the results depend on the processing

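The fits with the pool block and each pool left out, and the blocked correlation of MYBQKI6 with Qk suppression, were chosen after seeing the data. Directions held for all 60 calls of genes named for size under every alternative, except Dok7 with MYBQKI5, which stood at 0.10 when the probe set with the highest mean stood for the gene. The cause of the changes in counts was not tested. Counts for MYBtr, MYBQKI5 and MYBQKI6 against eGFP, in this order, were 1383, 609 and 1017 with the pool as a block, 1927, 1027 and 1481 with the pool as a random block over all 18 arrays (4 for MYBQKI5 against MYBtr), 835, 320 and 584 with 6 separate eGFP arrays, 182, 26 and 93 with the median over probe sets, and 100, 14 and 44 with the probe set of highest mean. Single probe sets gave 500, 176 and 305, with 6 for QKItr and 1 for MYBQKI5 against MYBtr. With only the 2 groups compared, MYBtr gave 37 and MYBQKI6 27. MYBQKI5 gave 70 after quantile normalization and 29 without dim probe sets. Qk suppression gave 0 with all 26 arrays in 1 fit, with the probe set of highest mean, with single probe sets, with samples of a first number averaged, with first number 5, 6 or 9 alone, and with 6 or 9 left out. Leaving out 1 pool or sample gave 52 to 456 (MYBtr), 11 to 32 (MYBQKI5), 23 to 244 (MYBQKI6), 0 to 0 (QKItr and MYBQKI6 against MYBtr), 0 to 3 (MYBQKI5 against MYBtr, the 3 without MYBtr of pool 3), 0 to 1 (MYBQKI6 against MYBQKI5, the 1 without MYBQKI6 of pool 1) and 0 to 1 (Qk suppression). With the pool block these were 566 to 1471, 134 to 377, 291 to 950, 0 to 0 for QKItr and MYBQKI6 against MYBtr, 0 to 21 and 0 to 1. Of the calls of named genes, 30 were lost with only the 2 groups compared, 28 besides Dok7 with the probe set of highest mean, 18 with the median over probe sets, 8 with all arrays, 8 without dim probe sets, 3 after centring, 2 with trend and robust, 1 after quantile normalization and 0 with the block, and leaving out 1 pool ended 153 calls over 6 fits each. Of 21 list calls, 18 were lost with an estimated correlation, 9 with the probe set of highest mean, 4 with the median over probe sets, and 0 after quantile normalization, centring or blocking, and with 1 pool or sample left out 14 list tests lost the call and 114 kept it. Spearman correlations between constructs were 0.595 (MYBtr with MYBQKI5), 0.635 (MYBtr with MYBQKI6) and 0.653 (MYBQKI5 with MYBQKI6). With 1 pool left out, Pearson correlations were 0.679 to 0.811, 0.714 to 0.852 and 0.690 to 0.852 for these pairs, -0.013 to 0.281, 0.096 to 0.394 and 0.014 to 0.294 for QKItr with MYBtr, MYBQKI5 and MYBQKI6, and -0.010 to 0.095 for MYBQKI6 with Qk suppression. Array signal near background limits what can be seen of dim genes.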

Other observations

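The genes in the first 2 paragraphs and the probe sets after them were chosen only after their values were seen. Beyond the genes named by rule, several genes with known roles in signalling and transcription were called with MYBtr, MYBQKI5 and MYBQKI6 and in the same direction. Sh3rf3, a scaffold protein with SH3 domains, rose by 2.41, 1.79 and 2.09 (limma adjusted p = 1.6e-04, 0.0021 and 5.8e-04). Batf3, a transcription factor of dendritic cells, rose by 1.66, 1.46 and 1.52, and Zbtb46, another transcription factor of that lineage, by 1.31, 0.97 and 1.06. Piwil4, a protein of the piRNA pathway, rose by 1.68, 1.32 and 1.74. Enpp1, an enzyme that makes pyrophosphate outside cells, rose by 1.54, 1.21 and 1.79, and Wasf3, a regulator of actin, by 1.89, 1.503 and 1.70. Mylip, a ubiquitin ligase, rose by 1.64, 1.19 and 1.40.

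Membrane proteins were also among these shared calls. Tmem108 rose by 1.94, 1.72 and 2.05, Itm2a by 1.73, 1.31 and 1.49 and Stom, which encodes stomatin, by 1.73, 1.15 and 1.28. Ankrd6, a protein of Wnt and planar polarity signalling, rose by 1.56, 1.20 and 1.58. Shared falls picked here were those of 3 genes: Ncam2, an adhesion molecule, stood at -0.75, -0.72 and -0.75, Ncoa1, a coactivator of nuclear receptors, at -0.78, -0.74 and -0.78, and Trim8 at -0.65, -0.69 and -0.68.

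Igtp, a GTPase induced by interferon that is in none of the fixed lists, differed by 2.39, 2.55 and 2.78 with MYBtr, MYBQKI5 and MYBQKI6 and was called only with the pool as a block (limma adjusted p = 0.11, 0.17 and 0.072, and 5.5e-05, 1.0e-04 and 3.5e-05 with the block).

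A set of 6 probe sets, 5 of which name no gene and 1 of which names Flnc, was called lower with MYBtr, MYBQKI5, MYBQKI6 and QKItr, and 4 of the 6 held distinct values. Their log2 signals were 9.57 to 13.7 in the 6 eGFP arrays and 2.94 to 6.93 in the 20 other arrays. Probe set 17549015 differed by -7.18, -6.92, -7.03 and -6.90 in the 4 comparisons. What these probe sets read was not tested, and a sequence of the vectors is not excluded, so these values are not shown to be those of a gene of the cells.

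The median and the mean of a list had opposite signs in 3, 5, 7 and 4 of 21 lists with MYBtr, MYBQKI5, MYBQKI6 and QKItr against eGFP. In MYBQKI5 against MYBtr, MYBQKI6 against MYBtr, MYBQKI6 against MYBQKI5 and Qk suppression this held for 4, 1, 5 and 3 lists. The mean and the camera direction were opposite in 0, 1, 1, 2, 2, 1, 0 and 2 lists in the same order, and 0 of all these lists were called.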
